A study of Mus musculus with 11 samples.

How the data were processed

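RNA was measured by sequencing in microglia (6 WT and 3 Mecp2-null libraries of 3 pooled mice each) and in resident peritoneal macrophages (1 library per genotype, 6 pooled mice each), from mice of 10 to 12 weeks. Per the labels, the cells were isolated acutely and sorted magnetically, and libraries were made from polyadenylated RNA. The submitters' processing notes name CASAVA, STAR 2.3.0, HTSeq, DESeq2 and the mm9 build. The authors deposited 1 file per library with raw read counts per gene symbol, and these deposited counts were whole numbers with no normalization. The microglia files listed 23284 mouse symbols. The macrophage files listed 23368 symbols, of which 23357 were in the capitals of human symbols and 15492 matched a microglia symbol when case was ignored.

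Counts were analysed in R 4.3.3 with edgeR 4.0.16. Microglia were fitted with edgeR's quasi-likelihood test after filterByExpr and TMM scaling, with genotype and library series as terms, and p-values were adjusted by the Benjamini-Hochberg method over the 14271 genes tested, with a threshold of 0.05. The series came from the library numbers in the file names, since the labels gave no batch. Series 44 held WT 1 and 2 and null 1 and 2, and series 61 held WT 3 to 6 and null 3. CPM values are means over libraries, and fold changes are those of the model, so these can differ where series differ. "SE" is the fold change's standard error.

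Gene lists of pathways and of markers of other cell types, and the rule for naming genes, were fixed before the data were examined. Of these, 46 had at least 4 tested members. Each was tested with camera in limma 3.58.1 on voom values with the same terms and a preset correlation between genes of 0.01, and the p-values were adjusted over the lists. Camera with an estimated correlation and fry were run beside it. Of the 11 lists past the threshold, none held with an estimated correlation, where 4 of the 46 had an unadjusted p under 0.05, and 7 of the 46, of which 4 were among the 11, passed with fry, which tests whether genes of a list move 1 way and not whether they differ from other genes. Members past the threshold were counted over all genes and adjusted over the list alone. Named genes were Mecp2, the 12 largest rises and 12 largest falls among called genes with a mean of at least 5 CPM in the higher genotype and the same direction in both series, up to 4 members with the smallest p of each list described, and Fkbp5, Sgk1, Tsc22d3, Irak1 and Slc38a1 whatever their values. The lists described in full, and the genes Clu and Syne1 in microglia, were picked after the results were seen.

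The macrophage libraries had no replicates, so no test was made. Log2 ratios were taken of TMM-scaled CPM with a prior count of 2, over genes with at least 10 CPM in the higher library, and the 10 highest and 10 lowest were named. Ratios without a prior are given with exact 95% intervals for counts, computed in R. Where a library had 0 reads the bound is against a floor of 3 counts in that library. The intervals and floors cover counting error only. List medians were set against 10000 random lists matched on mean expression. The macrophage libraries held 1615770 to 1747126 gene reads, so that 10 CPM was worth 17.5 reads in the WT library, and the microglia libraries held 13243334 to 21670443.

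The steps were tested on simulated data with known changes. Of 67 genes changed 1.5-fold, 36 were called, as were 49 of 67 changed 2-fold and 64 of 66 changed 4-fold, with 7 false calls among 156 and 0 with the wrong sign. The list test called the 1 shifted list and 0 of the others. Genes were drawn independently of each other there, so this could not show how often lists of correlated genes are called falsely. The draws also held no structure of the samples besides series and genotype. The shares of genes called and of false calls therefore need not hold for the real libraries. Counts of called genes and lists were also taken for all 84 splits of the 9 libraries into groups of 6 and 3.

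Alternatives tried for microglia were size factors by the median of ratios, library totals, no filter and a stricter filter, DESeq2 1.42.0, limma voom, no series term, replicate blocks, subsets of libraries, each library left out, a robust fit and a threshold of 0.1. Alternatives for macrophages were other scalings, prior counts and minimums. Those added after the data were seen were 3 library series, leaving out Rn45s, leaving out WT 6 with null 2, endothelial or immediate-early scores as covariates, some settings of the list test, and leaving out pancreatic enzyme genes. The planned comparison of microglia with macrophages and the model of all 11 libraries were left out, since the macrophage counts were listed on human gene symbols. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.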

Results

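RNA sequencing counts were available for 11 libraries of mouse cells: 6 wild-type (WT) and 3 Mecp2-null libraries of microglia, the resident macrophages of brain tissue, and 1 library per genotype of resident peritoneal macrophages. Mecp2 encodes a protein that binds methylated DNA. Each microglia library pooled 3 mice and each macrophage library 6 mice, aged 10 to 12 weeks. WT microglia libraries 1 to 6 held 13243334, 17762709, 21670443, 16379263, 16002558 and 17283683 reads assigned to genes, and null libraries 1 to 3 held 18620318, 18534296 and 15558605. The macrophage libraries held 1747126 (WT) and 1615770 reads (null). Library numbers formed a series 44 (WT 1 and 2, null 1 and 2, both macrophage libraries) and a series 61 (WT 3 to 6, null 3). The macrophage files listed human gene symbols and the microglia files mouse symbols, so levels were not compared between the cell types. Values are CPM, which are gene reads scaled to the size of each library, or log2 fold changes of null over WT, and genes are named by the symbols in the files. No genome coordinates are given, since the build named for the counts was not at hand.

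The first comparison asked which transcripts differed between null and WT microglia. Mecp2 itself measured 86.2 ± 8.83 CPM in WT (SD, n = 6) and 6.49 ± 1.25 CPM in null libraries (SD, n = 3). The WT libraries 1 to 6 gave 74.3, 77.3, 97.6, 87.2, 89.5 and 91.4 CPM, and the null libraries 1 to 3 gave 5.12, 6.78 and 7.56 CPM. The log2 fold change was -3.64 (SE 0.095; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 4.9e-08), with -3.66 within series 44 and -3.57 within series 61.

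Beyond Mecp2, the glucocorticoid-responsive gene Fkbp5 and the endothelial gene Cldn5 were among those that rose, and the choroid plexus gene Kcnj13, the MHC class II gene H2-Ab1 and the microglia gene Fcrls were among those that fell. Of 14271 genes tested, 941 rose and 714 fell, and 115 of the former and 124 of the latter changed at least 2-fold. The median change of the 1655 called genes was 1.41-fold. In 1319 of them the null and WT libraries did not overlap, though these genes were called on the same libraries. The same was so for 17.8% of all tested genes, where chance would give 2.38% if all libraries were interchangeable. The genotypes were spread unevenly over the series, so this was no test of chance.

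The genes with the largest rises were Stfa2l1, a cysteine protease inhibitor of the stefin family (log2 fold change 4.15), Doc2b, a calcium sensor of vesicle release (3.19), Hif3a, a hypoxia-inducible factor subunit (2.84), and Asprv1, an aspartic protease (2.83). Slc10a6, a transporter of steroid sulfates (2.61), Agxt2l1 (2.33), the secreted growth factor regulators Igfbp3 (2.28) and Ctgf (2.28), and Ccdc85a (2.07) followed. The calcium channel subunit Cacna1e (2.06), the myeloid inhibitory receptor Cd300lf (1.98) and the decarboxylase Ddc (1.82) completed the 12. Ctgf went from 16.5 ± 6.70 CPM (SD, n = 6) to 99.6 ± 68.3 CPM (SD, n = 3), and Ddc from 10.7 ± 3.39 to 41.1 ± 17.2 CPM. All 3 null libraries lay above all 6 WT libraries for 11 of these genes, Cd300lf being the exception (edgeR adjusted p = 0.00915 for Ctgf, the lowest of the 12, and 0.0402 for Igfbp3, the highest). Several had few reads in WT libraries, as for Stfa2l1 with 0.538 ± 0.32 CPM. Stfa2l1 (1.45, 12.6 and 11.3 CPM in null 1 to 3), Asprv1 (4.58, 45.9 and 20.7 CPM) and Cd300lf (8.51, 61.4 and 27.7 CPM) were highest in null 2 and 3. They were lower in WT 6 (1.16, 4.33 and 13.1 CPM) and WT 4 (0.428, 3.30 and 7.16 CPM). Markers of neutrophils were also higher in null 2 and 3 than in null 1. Relative to the WT mean, their median was -0.436, 0.712 and 1.02 in null 1 to 3. In WT 4 it was 0.973 and in WT 6 1.495, the latter above every null library. Their median log2 fold change was 0.66 over 12 genes, of which none passed over all genes or adjusted over the list alone (camera adjusted p = 0.0706), with 1.00 in series 44, where the list passed, as it did without WT 6 (0.89), and 0.29 in series 61. The marker Cxcr2 (1.51, edgeR adjusted p = 0.103) measured 7.22, 22.8 and 28.1 CPM in null 1 to 3 and 16.9 CPM in WT 6. Markers of monocytes had a median of 0.38 (camera adjusted p = 0.12), with 0.03 in series 44, where the test pointed down, and 0.78 in series 61, which held 1 null library. Of the 11, Fn1 (0.38) rose, as it did adjusted over the list alone, and the list was highest in WT 6 (1.32), null 3 (1.05) and null 2 (0.738).

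The genes with the largest falls included the potassium channel genes Kcnj13 (log2 fold change -2.52) and Kcne2 (-2.13), the insulin-like growth factor binding protein gene Igfbp2 (-2.28), the keratin gene Krt18 (-2.03) and the FGF co-receptor gene Kl (-1.94). Vat1l (-2.52), Fam40b (-2.31), Tmem72 (-1.88), the calcium pump gene Atp2b3 (-1.84), Epn3 (-1.79), the chloride channel gene Clic6 (-1.76) and the adenylate cyclase gene Adcy8 (-1.71) made up the rest. Igfbp2 went from 43.3 ± 20.4 CPM (SD, n = 6) to 9.14 ± 3.40 CPM (SD, n = 3). Kcnj13, Clic6 and Kl were on the fixed list of ependymal and choroid plexus markers, whose median was -1.27. All 3 null libraries lay below all 6 WT libraries for 10 of the 12, Tmem72 and Atp2b3 being the exceptions (edgeR adjusted p = 0.0131 for Igfbp2, the lowest, and 0.0488 for Tmem72, the highest).

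**Figure D1:**
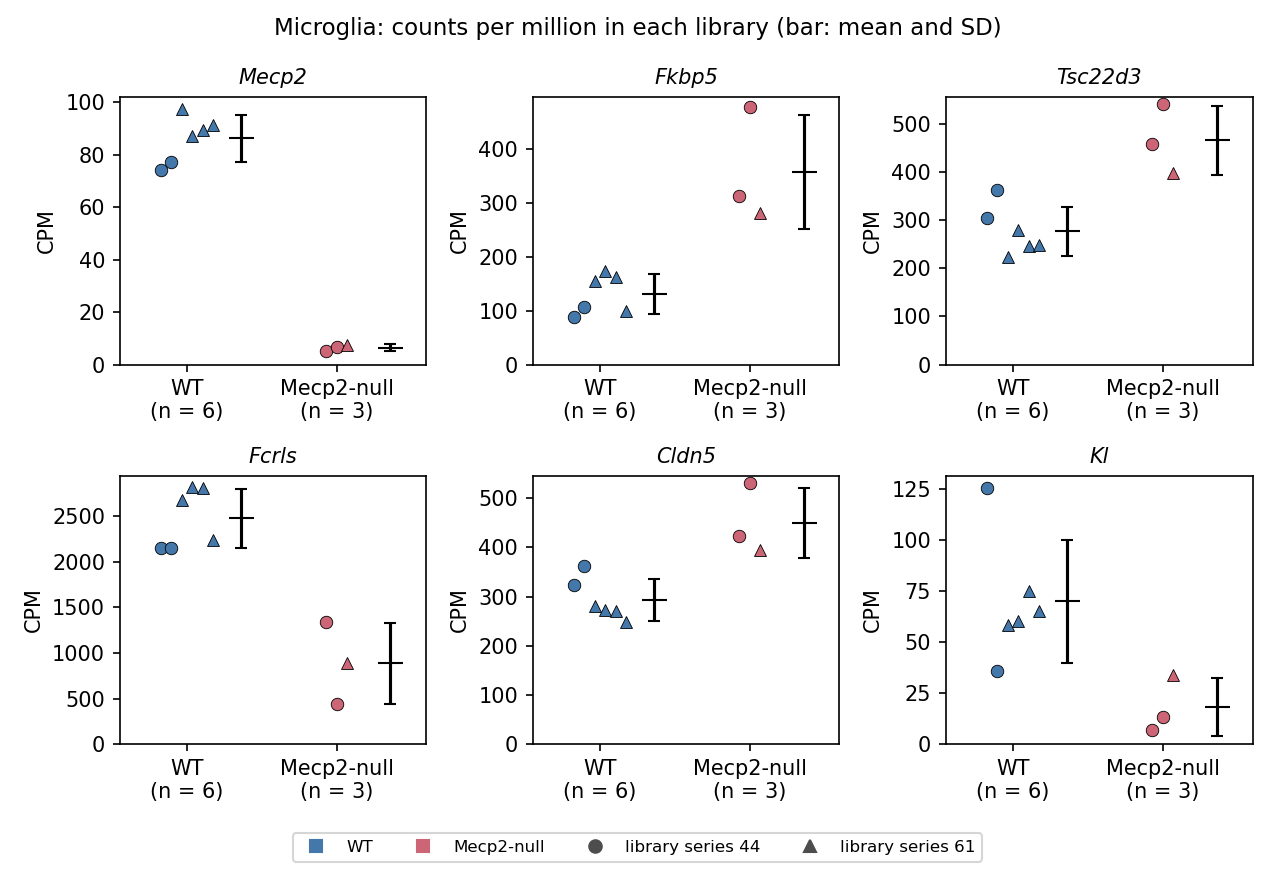
Gene levels in CPM (vertical axes, from 0) of Mecp2, Fkbp5, Tsc22d3, Fcrls, Cldn5 and Kl in the 6 WT and 3 Mecp2-null microglia libraries; points are libraries, their shape gives the library series, and the bars beside them are the mean and SD. The null libraries lie between 5.12 and 7.56 CPM for Mecp2, and for each of the 6 genes they do not overlap the WT libraries.

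Genes induced by glucocorticoid hormones rose as a group: 12 of 27 rose, none fell, and 15 rose when adjusted over the list alone. Fkbp5, a co-chaperone of the glucocorticoid receptor, went from 131 ± 37.2 CPM (SD, n = 6) to 358 ± 106 CPM (SD, n = 3), a log2 fold change of 1.57 (edgeR adjusted p = 0.0128, higher in 3 of 3 null libraries than in any WT library). Its log2 difference was 1.99 in series 44 and 0.97 in series 61. Tsc22d3, which encodes the anti-inflammatory protein GILZ (0.62, edgeR adjusted p = 0.0105), the phosphatase gene Dusp1 (0.82) and the clock gene Per1 (0.58) rose too, whereas Sgk1, a kinase gene of the same list, was at 0.17 (edgeR adjusted p = 0.479). The list median was 0.45 (camera adjusted p = 7.8e-06; adjusted p = 0.643 with an estimated correlation), with 0.59 in series 44 and 0.31 in series 61. Endothelial markers moved with this list, at a median of 0.54, and with their score as a covariate, which followed genotype closely, the list median was 0.11 and the call ended.

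Immediate-early genes, which are transcribed within minutes of a stimulus, also rose: 7 of 25 rose, none fell, and 11 rose adjusted over the list alone. Klf2 (0.85), Dusp1 (0.82), Jund (0.57) and Ier2 (0.53) were the members with the smallest p. The list median was 0.34 (camera adjusted p = 1.3e-05; adjusted p = 0.473 with an estimated correlation), with 0.26 in series 44 and 0.43 in series 61. It moved with the endothelial markers, at 0.54, and with their score as a covariate the median was 0.10 and the call ended.

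Markers of endothelial cells, which line blood vessels, were higher as a group: 13 of 15 rose, and all 15 rose adjusted over the list alone. The tight junction gene Cldn5 went from 293 ± 41.7 CPM (SD, n = 6) to 450 ± 71.5 CPM (SD, n = 3), a log2 fold change of 0.51, and Egfl7 (0.76), the VEGF receptor gene Flt1 (0.59) and the adhesion gene Esam (0.57) rose as well. The list median was 0.54 (camera adjusted p = 4.08e-10, higher in 3 of 3 null libraries than in any WT library; adjusted p = 0.51 with an estimated correlation), with 0.50 in series 44 and 0.61 in series 61.

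Markers of the ependyma and choroid plexus, the epithelium that makes cerebrospinal fluid, moved the other way. Kcnj13, Clic6 and Kl fell, the other 7 of 10 did not pass the test, and 8 fell adjusted over the list alone. Folr1, a folate receptor gene, was at -1.41 (edgeR adjusted p = 0.0533). The list median was -1.27 (camera adjusted p = 0.000744, lower in 3 of 3 null libraries than in any WT library; adjusted p = 0.473 with an estimated correlation), with -2.24 in series 44 and without null 3, and -0.93 in series 61. Relative to the WT mean, WT 1 had the highest list median of the WT libraries (0.926, the others from -0.619 to 0.072), and the list's median log2 fold change was -0.85 without it. Markers of natural killer cells had a median of -2.35 (camera adjusted p = 0.0107; adjusted p = 0.799 with an estimated correlation) over 9 genes, with -3.14 in series 44 and -1.37 in series 61. The call ended within series 61, without WT 1 (-2.17), WT 2 (-2.19) or null 2 (-1.86), without the series term and with the stricter filter, and the median was -1.43 without WT 6 and -0.78 without WT 6 and null 2 together, where the call held. Relative to the WT mean, null 3 (-0.751) lay above WT 3, 4 and 5 (-1.52, -1.35 and -1.53). Gzmb, a protease gene of cytotoxic cells, did not pass (edgeR adjusted p = 0.124) and ranged from 1.49 to 17.8 CPM among WT libraries and from 0.51 to 2.18 CPM among null libraries.

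Among genes that mark microglia at rest, Fcrls, an Fc receptor-like gene, fell from 2475 ± 328 CPM (SD, n = 6) to 889 ± 445 CPM (SD, n = 3), a log2 fold change of -1.40 (edgeR adjusted p = 0.022, lower in 3 of 3 null libraries than in any WT library). Olfml3 fell by 1.33 on the log2 scale, whereas Ltc4s, an enzyme of leukotriene synthesis, rose by 0.52 and the lipid receptor gene Trem2 was at -0.32 (edgeR adjusted p = 0.0696). Of the 23 list members 1 rose and 2 fell, and 1 rose and 8 fell adjusted over the list alone. The list median was -0.32 (camera adjusted p = 0.000435; adjusted p = 0.799 with an estimated correlation), with -0.35 in series 44 and -0.21 in series 61. Relative to the WT mean, null 2 stood apart with a list median of -0.847, while null 1 (-0.195) lay beside WT 1 (-0.157) of its series. Null 3 (-0.163) lay below the WT libraries of its series, which ranged from -0.036 to 0.117. The list's median log2 fold change was -0.17 without null 2. The list fell while the endothelial markers rose, at a median of 0.54, and with the endothelial score (0.32) or the immediate-early score (0.235) as a covariate, which both followed genotype closely, the list passed pointing up.

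Genes of MHC class II, which present antigen to T cells, fell: H2-Eb1 (-0.57), H2-Ab1 (-0.52), H2-Aa (-0.50) and Cd74 (-0.36) fell among 10, none rose, and 6 fell adjusted over the list alone. H2-Ab1 went from 232 ± 34.3 CPM (SD, n = 6) to 151 ± 19.3 CPM (SD, n = 3). The list median was -0.43 (camera adjusted p = 0.000405; adjusted p = 0.51 with an estimated correlation), with -0.48 in series 44 and -0.30 in series 61. The call ended with the endothelial or the immediate-early score as a covariate (-0.12 with each), both of which followed genotype closely. Markers of other antigen-presenting cells had negative medians without passing the list test, and not in every null library or series. Those of dendritic cells had a median of -0.48 (camera adjusted p = 0.496), with -0.12 in series 44 and -0.77 in series 61. Relative to the WT mean, null 2 (0.199) lay above every WT library on this list, while null 1 (-0.314) and null 3 (-0.739) lay below every one. Of the 11 dendritic markers, Cd209a fell (-1.22, edgeR adjusted p = 0.0196), and 2 fell adjusted over the list alone. Those of B cells had a median of -0.46 (camera adjusted p = 0.12), with -0.79 in series 44, where the list passed, and 0.19 in series 61. Of the 7, Cd22 fell (-0.91, edgeR adjusted p = 0.00915), as it did adjusted over the list alone. Lysosomal genes had a median of -0.15 (camera adjusted p = 0.0244; adjusted p = 0.831 with an estimated correlation). Of the 28, the proteases and hydrolases Ctsd (-0.59) and Hexa (-0.71) and the membrane protein gene Cd63 (-0.41) fell and the galactosidase gene Gla (1.09) rose, with 7 falling and 1 rising adjusted over the list alone. The lysosome call ended within series 44 and without null 3 (-0.13), which left genotype compared within series 44 alone. It also ended without WT 3, 4 and 5, with the block by file names, with 3 library series, and without null 2 (-0.10).

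Ribosomal protein genes had a median of 0.26 (camera adjusted p = 2.39e-06; adjusted p = 0.686 with an estimated correlation), with 0.32 in series 44, 0.14 in series 61 and 0.16 without WT 6 and null 2 together. Of the 56, Rpl13 (0.46), Rpl12 (0.46) and Rps18 (0.41) rose, and 1 rose adjusted over the list alone. Cholesterol synthesis genes had a median of 0.16 (camera adjusted p = 0.00634; adjusted p = 0.686 with an estimated correlation). The call ended within series 44 (0.10) and without null 3 (0.10), which left genotype compared within series 44 alone. It also ended with the endothelial (0.06) or the immediate-early score (0.03) as a covariate. Of the 20, Insig1 (0.59), a sterol sensor, Lss (0.63) and Sc5d (0.29), both enzymes of the pathway, rose, and 4 rose adjusted over the list alone. Heat shock genes had a median of -0.21 (camera adjusted p = 0.024; adjusted p = 0.799 with an estimated correlation). The call ended within series 61 (-0.11), without the series term (-0.02), without WT 1 (-0.17), WT 2 (-0.17) or null 2 (-0.07), and without WT 6 and null 2 together (-0.10). Hsph1 alone fell among 15 (-0.40), as it did adjusted over the list alone, although its group means were 207 and 206 CPM, since the model compared libraries within series.

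Other lists did not pass the list test. Glycolysis genes had a median of -0.15 (camera adjusted p = 0.12), where Pfkl (-0.40), Tpi1 (-0.42) and Aldoa (-0.41), enzymes of the pathway, fell with 2 others, and the glucose transporter gene Slc2a1 (0.80) rose, with the same counts adjusted over the list alone. Glutamate handling genes had a median of 0.13 (camera adjusted p = 0.0572), where Glul, which makes glutamine, rose by 0.37 and Slc38a2, Slc1a1 and Got1 rose as well (5 adjusted over the list alone), while the glutamine transporter gene Slc38a1 was at -0.04 (edgeR adjusted p = 0.719). The glutamate list stayed short of the threshold in 18 of 25 other settings and passed in the rest. Genes of disease-associated microglia had a median of 0.12 and a mean of 0.17 where the list test pointed down (camera adjusted p = 0.843). Of these, Cst7 (-0.95), Ctsd and Itgax (-0.49) fell with 1 other and Ccl6 (0.53) rose, and 5 fell and 3 rose adjusted over the list alone. Of DNA replication genes on the cell cycle list, Pcna, Mcm7, Mcm6 and Mcm2 rose by 0.54, 0.45, 0.29 and 0.27, while the list median was -0.06 and the test pointed up (camera adjusted p = 0.604; 4 rose adjusted over the list alone). This list passed, pointing up, within series 44 (0.19) and pointed down within series 61 (-0.35). Interferon response genes (median -0.002, camera adjusted p = 0.967) held 1 gene that rose, Mx1 (0.72), and 2 that fell, Oas2 (-0.68) and Oas1a (-0.50), the same counts as adjusted over the list alone. Genes of the TNF response held Tnf (0.58), which rose, and Nfkbie (-0.45), which fell (camera adjusted p = 0.861; 1 fell adjusted over the list alone). Genes earlier reported as Mecp2 targets had a median of 0.20 (camera adjusted p = 0.0706), with Id3 (0.71), Id1 (1.00), Fkbp5 and Irak1 (0.34) among the 5 of 13 that rose, and 5 rose and 1 fell adjusted over the list alone. Of 38 X-linked neighbours of Mecp2, Irak1, Dnase1l1 (0.53), Haus7 (0.47) and Flna (0.34) rose (6 adjusted over the list alone), and the list median was -0.05 while the test pointed up (camera adjusted p = 0.983). Within series 44 the test pointed up for the disease-associated list (0.26) and down for the X-linked list (-0.001).

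**Figure D2:**
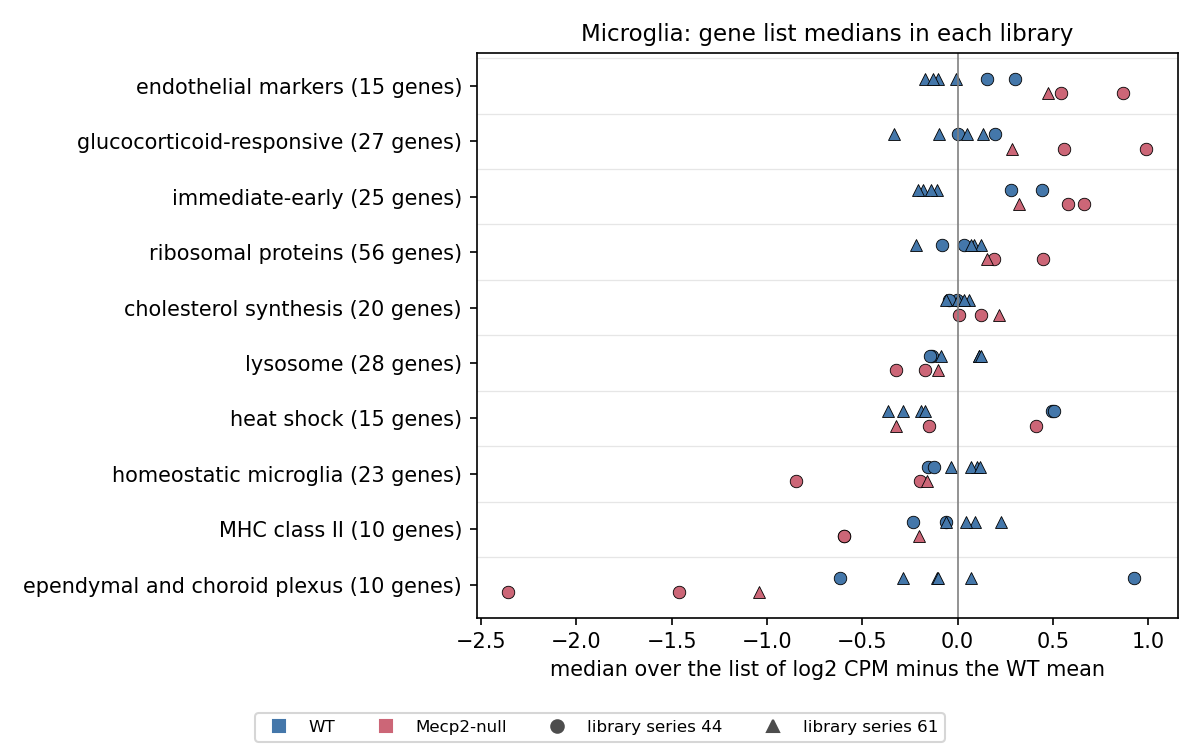
Median over each gene list of log2 CPM minus the mean of the 6 WT libraries (horizontal axis), for 10 gene lists (vertical axis) in each of the 9 microglia libraries; colour gives genotype and shape gives library series. The 3 null libraries lie above every WT library for endothelial markers and below every WT library for ependymal and choroid plexus markers.

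The count of called genes depended on single libraries: it was 1 (Mecp2) without null 3, 254 without WT 1, 567 without WT 2, 819 without WT 3, 958 without WT 4, 878 without WT 5, 636 without null 2 and 2750 without null 1, and it was 1 within series 44, 161 within series 61 and 1 with the endothelial or the immediate-early score, both of which followed genotype closely, as a covariate. Series 61 held 1 null library, which was assumed there to vary like the WT libraries. Without null 3, the series term left genotype compared within series 44 alone. The count of 1 in that setting therefore does not show how far the values of null 3 drive the calls. Of the 11 lists, 6 passed with the endothelial score, where heat shock (0.195), homeostatic microglia and lysosomal genes (0.185) pointed up, against the reported direction, and the choroid plexus, natural killer and ribosomal protein lists kept theirs. With the immediate-early score only the homeostatic list passed. In simulated counts of this design, 53.7% of genes changed 1.5-fold, 73.1% of those changed 2-fold and 97.0% of those changed 4-fold were called. The simulated counts held no structure of the samples besides series and genotype, so these shares need not hold for the real libraries.

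The second comparison asked which transcripts differed between null and WT peritoneal macrophages. It held 1 library per genotype, so no test was made, and intervals are 95% intervals of counting error alone. MECP2 had 204 reads in the WT and 25 in the null library, a CPM ratio of 0.134 (interval 0.0844 to 0.203). FKBP5 was higher in the null library, with 25 and 80 reads and a ratio of 3.49 (2.20 to 5.70), as were SGK1, with a ratio of 1.40 (1.04 to 1.90), and TSC22D3, with 1.13 (1.06 to 1.21). IRAK1, a kinase gene of Toll-like receptor signalling, was lower, with a ratio of 0.690 (0.536 to 0.884). SLC38A1 had 14 and 7 reads and was under the minimum of 10 CPM.

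The 10 genes with the highest ratios all encoded digestive enzymes, or close relatives of them, that the exocrine pancreas secretes. The amylase gene AMY2B had 1 read in the WT and 2103 in the null library, a ratio of 2291 (411 to 90500). The other 9 had 0 reads in the WT library, and against a floor of 3 counts in that library the trypsinogen gene PRSS1 (437 reads in null) was at least 159-fold higher and CTRB2 at least 143-fold. CPA1, CELA1, AMY2A, PNLIPRP1, TRY6, PRSS3 and CPA2 were at least 116-, 108-, 94.4-, 94.4-, 77.3-, 74.8- and 49-fold higher. Reads of such paralogs cannot be assigned to 1 gene with certainty, and whether they came from the macrophages or from pancreatic tissue in the null sample was not tested. On a list of pancreatic enzyme genes written after these values were seen, all 17 with at least 10 CPM were at least 2-fold higher, and the 42 genes together took 3 WT and 5053 null reads, 0.313% of the null library.

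The genes with the lowest ratios were CEBPE, a factor of granulocyte maturation (35 and 1 reads, ratio 0.0311, 0.000766 to 0.185), the gelatinase gene MMP9 (44 and 2 reads), INPP5J (24 and 1 reads), MECP2, CTNND2 (29 and 3 reads), HLA-DQB2 (30 and 4 reads), HLA-DRB6 (61 and 10 reads), TESC (18 and 2 reads), SEPT1 (37 and 6 reads) and SYNE1 (22 and 3 reads). Of the 10 MHC class II genes on the fixed list, only 2 matched a symbol of the macrophage files by name. Of these, CD74 alone reached 10 CPM, with 59 and 17 reads and a ratio of 0.314 (0.172 to 0.546). Further class II symbols, chosen after their values were seen, were lower too: HLA-DQB1 had 929 and 259 reads, HLA-DRB1 345 and 84, and HLA-DQA1 159 and 47. Reads of such similar genes cannot be assigned to 1 symbol with certainty, so the HLA symbols need not count as separate genes. The chemokine receptor gene CCR2, a marker of monocytes and small peritoneal macrophages, had 39 and 7 reads. The T cell marker LCK had 47 and 14 reads. Of dendritic cell markers, CCR7 had 37 and 14 reads and FSCN1, which was higher, 163 and 223.

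Of 26 gene lists, 5 had a median log2 ratio above and 5 below the central 95% of 10000 random lists matched on expression. Random lists hold unrelated genes, so a list whose genes vary together can leave this range through any difference between the libraries. The range is therefore no test of genotype. Glucocorticoid-responsive genes had a median of 0.41 (random lists -0.14 to 0.15), with FKBP5 and DDIT4, an inhibitor of mTOR signalling (27 and 57 reads), at least 2-fold higher among 13. Markers of large peritoneal macrophages had a median of 0.38, with the lubricin gene PRG4 (3608 and 5885 reads, ratio 1.78) and the fibronectin gene FN1 (36903 and 44982 reads, ratio 1.33) higher. Complement and phagocytosis genes had a median of 0.28, hypoxia genes 0.27 and alternative activation genes 0.41. Immediate-early genes had a median of -0.44 (random lists -0.12 to 0.14), with EGR2 (24 and 5 reads), EGR3 (27 and 9), NR4A2 (41 and 16) and NR4A1 (29 and 12) at least 2-fold lower. Cholesterol synthesis genes had a median of -0.65 (random lists -0.30 to 0.33), with HMGCS1 (65 and 21 reads) and LDLR (33 and 12), an enzyme of the pathway and the LDL receptor, at least 2-fold lower. Heat shock genes (-0.38), with HSPA5 at 7959 and 4801 reads, glycolysis genes (-0.23) and endoplasmic reticulum stress genes (-0.18) were lower as well.

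In all, 103 of 6455 genes with at least 10 CPM in the higher library were at least 2-fold higher in the null library and 125 were at least 2-fold lower. Counting error alone gave 49.3 such genes in the mean of 100 draws and 68 at most, and with no replicates the spread between animals was not measured.

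The third comparison set the genotype differences of the cell types side by side. MECP2 was lower and FKBP5 higher in null cells of both. Over 684 genes called in microglia and measured in both, Mecp2 left out, the microglia log2 fold change and the macrophage log2 ratio correlated across genes with Pearson's r = 0.18 and Spearman's rho = 0.203. The direction was shared by 424 of them (62.0%, against 51.0% from the shares of each direction). Over all 5799 genes measured in both, r was 0.132, rho was 0.157 and 56.0% shared the direction, against 50.1%. Genes are not independent replicates, and r over the called genes was 0.092 without WT 2 and 0.372 with a minimum of 50 CPM, while too few genes were called within series 44 for a value.

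**Figure D3:**
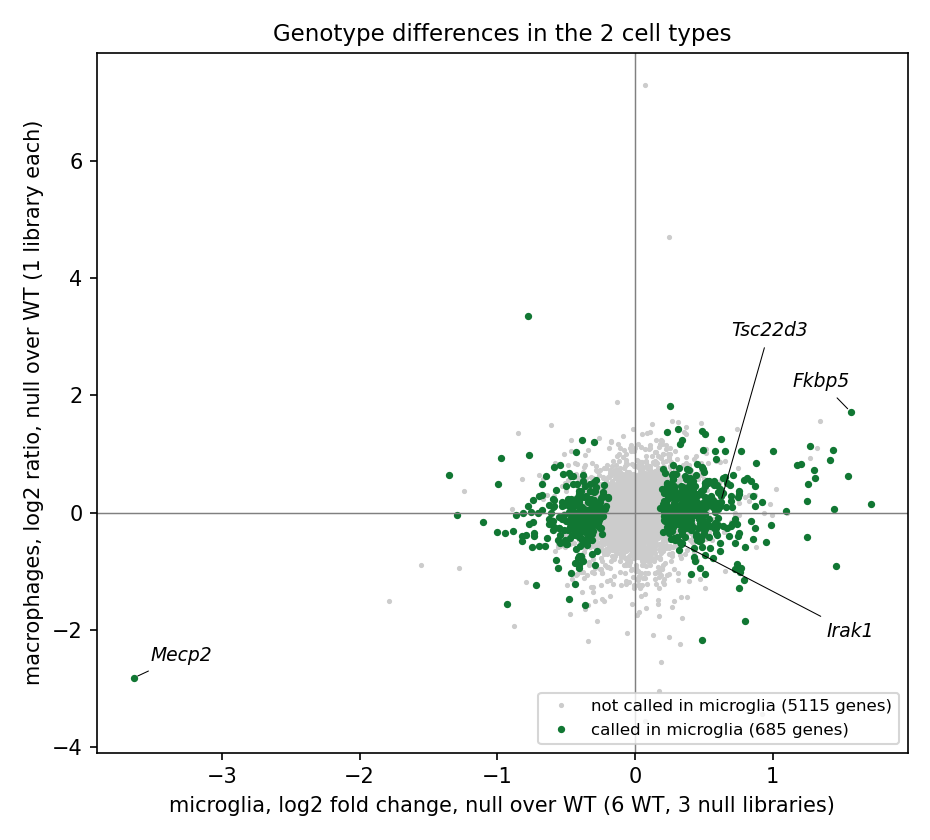
Log2 fold change in microglia (horizontal axis, 6 WT and 3 null libraries) against log2 ratio in peritoneal macrophages (vertical axis, 1 library per genotype) for genes measured in both; green points passed the test in microglia, and Mecp2 is drawn though left out of the correlation. Mecp2 lies at -3.64 and -2.81 and Fkbp5 at 1.57 and 1.72.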

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

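Of the tests below, those of a lower microglia share, of endothelial RNA carrying glucocorticoid-responsive transcripts, of a handling response, of mouse reads on human gene models and of the splits of the libraries were chosen only after the result was seen.

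Endothelial genes were higher and choroid plexus genes lower in null microglia libraries. A lower share of microglia alone would raise markers of all other cell types alike. The choroid plexus median of -1.27 beside the endothelial median of 0.54 is unlike that. These values are the pattern itself, so they were no separate test. Medians of neuron (-0.43), astrocyte (-0.30), oligodendrocyte precursor (-0.085), oligodendrocyte (0.03) and pericyte markers (0.11) went both ways, none passing the list test. A lower share together with less choroid plexus RNA stays open. More endothelial RNA may account for the first part, since a second list of 33 vascular genes had a median of 0.469 with 93.9% above 0, and less choroid plexus RNA for the second part, since a second list of 23 genes had a median of -1.18 with 82.6% below 0. The labels name a magnetic sort, which would remove both kinds of cell where it is complete, and abundant markers were present in WT libraries too, with Flt1 at 478 and Cldn5 at 293 CPM. Whether the cells differed in number or in expression, in the tissue or in the sort, stays open, as does an effect of genotype.

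Glucocorticoid-responsive genes were higher in null microglia libraries. Endothelial RNA carrying these transcripts cannot be told apart from a change in microglia, since the 12 called members had a median of 0.897, whose interval of 0.619 to 1.64 included the bound of 0.729 set by the endothelial markers. Of the 12, 7 lay above that bound, but these genes were picked for their rise. Genes of the second vascular list, whose median was 0.469, lay above it too, such as Foxq1 (0.981), Slc19a3 (0.929) and Robo4 (0.898). Lying above the bound therefore could not decide the source. A stronger response to cell handling in the null libraries cannot be told apart either: with the immediate-early score as a covariate the median was -0.083, but that setting left 1 of 1655 gene calls, so the score followed genotype too closely for a test. The same holds for the endothelial score, with which the median was 0.107 and the list call ended. An effect of genotype on hormone levels or on microglia was not tested and stays open.

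The macrophage files listed human gene symbols. RNA of human cells was argued against, since 41.2% of 51 nuclear genes of oxidative phosphorylation had fewer than 3 counts in both libraries. Mouse reads counted on human gene models may account for it, since 27 genes that diverge between the species had a median log2 ratio of macrophage to microglia CPM of -5.03 and 30 conserved genes one of 2.27, a difference of -7.3. B2M had 1 and 4 reads. No biological explanation was tested. If mouse reads were counted on human gene models, levels in these files would depend on how well the reads match each human gene.

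Of the 84 splits of the 9 libraries, 2, the real one among them, gave at least 1655 called genes. The splits were not held to the make-up of the real groups by series. A split that mixes null with WT libraries also counts their difference as spread, which works against calls. Chance as the reason for the called genes was therefore not excluded. The highest of the other splits, null 2, null 3 and WT 6 against the rest, called 2149, more than the real split, which points to a structure of the samples besides genotype. Nor was chance excluded for the 11 gene lists, since 63 of the 84 splits, the real one among them, gave as many. The highest other gave 23. The endothelial median was the highest of the 84 splits (0.46 in the next). In 2 other splits, both with another make-up by series, the glucocorticoid median was as high as the real one.

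A library stood far from the rest of the 6 WT microglia libraries in 18 of 157 measures tested, 8 times WT 1 and 10 times WT 6. Chance gives about 1 in 20 for a single measure. The measures were not independent, since Kcnj13, Clic6 and Folr1, for example, are on the same marker list. The WT libraries also came from both series, so the count is not a test. The null group of 3 was too small for this rule. WT 6 had 23.8% of reads outside genes, 22.8% of genes at 0, 12.8% of reads in its 10 top genes and 6.74% in the ribosomal RNA gene Rn45s. It also stood apart for Stfa2l1 (1.16 CPM), Ccl6 (154 CPM), Itgax (51.3 CPM), Mmp9 (85.0 CPM), and the medians of the TNF response list (-0.216) and the oxidative phosphorylation list (-0.232). WT 1 stood apart for Kcnj13 (25.2 CPM), Vat1l (46.2 CPM), Igfbp2 (83.5 CPM), Kcne2 (28.3 CPM), Epn3 (13.3 CPM), Clic6 (70.5 CPM), Folr1 (28.2 CPM) and Ndufa3 (27.6 CPM).

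Some results went one way in microglia and the other way in macrophages, a difference that was not tested. Of 43 called genes that were named by rule in either cell type or afterwards and measured in both, Irak1, Jund, Slc2a1 and Syne1 rose in microglia and had macrophage ratios of 0.690, 0.580, 0.661 and 0.149. Clu fell in microglia and had a macrophage ratio of 29.4, from 1 and 27 reads. The immediate-early list, where 7 of 25 genes rose in microglia, had a macrophage median of -0.442, and the cholesterol synthesis list, where 3 of 20 rose, had one of -0.648. In microglia both passed camera's list test, but not with an estimated correlation (adjusted p = 0.473 and adjusted p = 0.686 with an estimated correlation).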

How the results depend on the processing

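The 2 score covariates, 3 library series, the fits without Rn45s and without WT 6 with null 2, and some settings of the list test were chosen after the data were seen. The log2 fold change of Mecp2 in microglia kept its direction and passed the threshold in every setting run, between -4.10 and -3.54. The count of 1655 genes became 20 with a block by replicate number, 104 without WT 3, 4 and 5, 681 with a block by a word the file names share, 1 within series 44, 161 within series 61, 3109 at a threshold of 0.1, and 1 with either the endothelial or the immediate-early score. Fewer libraries or a wider threshold belong to some of these settings by construction; for the others the cause was not tested. Leaving out 1 library gave 1 (without null 3, where genotype was compared within series 44 alone) to 2750 (without null 1). Without WT 6 the count was 2372. The count of 11 lists became 0 with an estimated correlation, 7 with fry (4 of the 11 and 3 others), 19 with the block by number, 18 with the file name block, 20 within series 44, 18 with 3 library series and 6 with the immediate-early score, and 8 to 18 with 1 library left out. From the block by number on, these held 11, 10, 9, 10 and 1 of the 11, and 8 to 11 with 1 library left out. Of the 11, the endothelial, immediate-early, choroid plexus and MHC class II lists passed with fry. The glucocorticoid list, for example, did not (fry adjusted p = 0.0585). The macrophage count of 228 became 413 at 5 CPM and 45 at 50 CPM, which changed how many genes were counted, and 211 without pancreatic enzyme genes. The correlation of effects became 0.372 at 50 CPM and 0.092 to 0.228 with 1 library left out, with no value within series 44 or without null 3, where too few genes were called.

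Replicate numbers did not pair the libraries: same-number correlations of null and WT libraries were -0.051, 0.292 and 0.21, against 0.508 for null 3 with WT 6. With series removed the same-number values were -0.376, -0.258 and -0.251. Null 3 then had 0.394 with WT 6 and 0.681 with WT 1. The block by number, which called 20 genes, therefore stood as an alternative only, as fixed before the data were examined. WT 4, 5 and 6 shared their number with no null library, so they did not enter its comparison of genotypes. The block by a file name word put WT 1 with null 1, WT 2 with null 2 and WT 6 with null 3. The correlation of 0.508 thus belongs to a pair of that block. It left WT 3, 4 and 5 without a partner and out of its fit, which called 681 genes. Whether these words mark libraries prepared together was not tested.

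Of 3361 comparisons of single genes in microglia, 2326 were the same, 892 weaker, 85 stronger and 58 reversed, and of 650 for lists 554, 40, 46 and 10. A reversal was counted only for a result past the threshold as reported. Of 282 macrophage gene comparisons 281 were the same, FN1 moving from 0.409 to 0.381 with size factors by the median of ratios, as were all 51 list comparisons. Every reversal so counted came under the 2 score covariates, which each left 1 of 1655 calls and followed genotype too closely for a reversal to be read as an effect of the score; the cause was not tested. With the endothelial score the reversed log2 fold changes were Irak1 -0.062, Stfa2l1 -0.58, Asprv1 -1.42, Agxt2l1 -0.66, Cacna1e -1.52, Cd300lf -1.92, Ddc -0.14, Adcy8 0.071, Hsph1 0.0995, Mx1 -0.28, Fcrls 0.22, Olfml3 0.44, Ctsd 0.18, Hexa 0.41, Xbp1 0.014, Slc1a1 -0.38, Flna -0.12, Syne1 -0.19, Fn1 -0.16, Cd209a 0.13, and the list medians heat shock 0.20, homeostatic microglia 0.32, lysosome 0.18. With the immediate-early score they were Irak1 -0.042, Stfa2l1 -0.87, Doc2b -0.94, Hif3a -0.13, Asprv1 -0.67, Slc10a6 -0.49, Agxt2l1 -0.96, Igfbp3 -0.13, Ccdc85a -0.73, Cacna1e -1.89, Cd300lf -1.40, Ddc -0.18, Kcnj13 0.38, Atp2b3 0.056, Adcy8 0.87, Tnf -0.20, Jund -0.11, Ier2 -0.23, Hsph1 0.031, Oas2 0.066, Mx1 -0.31, Fcrls 0.21, Olfml3 0.29, Ctsd 0.18, Hexa 0.26, Cd63 0.033, Slc2a1 -0.0067, Aldoa 0.019, Fas -0.34, Slc1a1 -0.27, Id3 -0.14, Id1 -0.0303, Flna -0.24, Esam -0.12, Cldn5 -0.10, Flt1 -0.12, Syne1 -0.27, Fn1 -0.30, and the list medians glucocorticoid -0.083, immediate-early 0.046, heat shock 0.076, homeostatic microglia 0.23, lysosome 0.079, ribosomal protein 0.011, endothelial -0.12. The homeostatic list passed pointing up with either score, and the heat shock and lysosome lists did with the endothelial score. The immediate-early and ribosomal protein medians stayed above 0 while the test pointed down. Among results not past the threshold, 34 of 330 list comparisons outside the score covariates changed the direction of the list test, over 7 of 15 lists, and 3 of 866 gene comparisons changed direction. The cell cycle list, for example, pointed down without the series term (-0.122), and it passed with the block by number (0.153, pointing up). Not run were the comparison of microglia with macrophages and its alternatives and the model of all 11 libraries. In the macrophage files 53.5% to 53.9% of symbols had 0 reads, for which the cause was not tested, and 10 CPM was worth 17.5 WT reads.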

Other observations

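The test of gene span was chosen only after the result was seen.

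Endoplasmic reticulum stress genes went both ways in null microglia. Atf4, a factor of the integrated stress response, rose by 0.49, while Creld2 (-0.43), the disulfide isomerase gene Pdia4 (-0.38) and Xbp1 (-0.29), a factor of the unfolded protein response, fell, and 5 rose and 10 fell of 21 adjusted over the list alone. The list did not pass (median -0.29, camera adjusted p = 0.329). In macrophages, the list median was -0.18, with PDIA4 at 535 WT and 353 null reads. Of 22 apoptosis genes, Mcl1, which blocks cell death, rose by 0.49 and the death receptor gene Fas by 1.07, and 3 rose adjusted over the list alone (median 0.05, camera adjusted p = 0.4). The 50 nuclear genes of oxidative phosphorylation had a median of -0.05 (camera adjusted p = 0.12).

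A hypothesis that longer genes rise in null microglia was tested over 12886 genes with a known span, taken by symbol from the GENCODE M21 annotation of the GRCm38 build, whereas the counts were made on mm9. Spearman's rho of log2 fold change with span was 0.0367 across genes, and 28 of the 84 splits of the libraries, the real one among them, gave one as high, the highest other being 0.177, so the data did not decide it.

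In the macrophage files GCG, the gene of the islet hormone glucagon, had 0 WT and 29 null reads, at least 10.5-fold higher, and CLU had 1 and 27 reads. In microglia Clu fell by 0.78 on the log2 scale (edgeR adjusted p = 0.00983, lower in every null library than the WT mean of its series). GCG and CLU were chosen after their values were seen.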
